A study of Caenorhabditis elegans with 2 samples.

How the data were processed

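Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans larvae in which the lin-1 gene carried an inserted GFP tag, so that the tagged protein was pulled down, per the labels' description, with an antibody against GFP. The antibody field of the labels reads lin-1 instead, and which of these was used was not resolved here. Per the labels, animals were synchronised by starving freshly hatched larvae after bleaching and were collected as L4 larvae at 48 hours, and chromatin was sheared by sonication. The series holds 1 group with 2 replicates, which the labels call biological replicates. A control experiment is named in the labels and was not used here.

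The values analysed are peak lists on the ce11 assembly, per the labels. Peaks were ranked by the irreproducible discovery rate (IDR), a measure of how alike the ranks of a peak are in a pair of lists, per the names and layout of the deposited lists. The peak caller, the aligner and their versions are not given in the sources used here, and neither are the read depths of the replicates. The lists are 4 ranked lists and 4 thresholded lists. Each replicate has its own pair, and the series has a pair for a comparison of the replicates, called conservative here as in its deposited name, and another pair, called the series list here. The authors gave each peak a score, which runs from 830 to 1000 in the thresholded conservative list, and a signal value whose scale is not stated. The signal is the authors' own value for a peak and was used here to describe, rank or filter peaks within a list. It was also compared between peaks with and without the ETS motif, and between the lists from which the conservative list was made. The ranked lists also hold the −log10 of the global IDR of each peak, deposited by the authors. A check of every thresholded list against its ranked list showed that it holds the ranked peaks at a global IDR of 0.01 or less, less a number of regions that were left out of it. In the conservative list 132 peaks carry the same pair of replicate signals as a stronger peak; they were kept in the main values. Replicates were called separately for their own lists, and both enter the conservative and the series list.

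The conservative list was the main list. Positions were set against the WBcel235 reference sequence, which is the same assembly as ce11, and the Ensembl 115 annotation of it. A check of all chromosome lengths found no peak beyond the end of a chromosome. A summit is the single position of highest signal that the list gives for a peak. Coordinates are 1-based.

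Overlap of 1 bp or more between replicate peaks was set against 1000 random placements of the replicate 1 peaks on their own chromosomes. The share of summits in promoter windows (1000 bp upstream to 200 bp downstream of a protein-coding gene start) and the share of autosomal summits in the middle 50% of a chromosome were set against 1000 placements each. The share of summits on X was tested with an exact binomial test. Motifs were counted on either strand in windows of 101 bp centred on the summit, and in windows of the same size centred 500 bp to each side, with Fisher's exact test. The same test was run for each 8-mer present in 10 or more windows, with its reverse complement counted as the same word. Mean log2 signal with and without the ETS motif was compared with a permutation test of 100000 resamples. For 33 gene lists fixed before the data were examined, members with a promoter summit were compared with all other protein-coding genes of the nuclear chromosomes by Fisher's exact test. Gene biotypes with 20 or more genes were compared with protein-coding genes in the same way, with a gene counted when a summit lay within 200 bp of it. Tests were two-sided except that of the overlap, which was one-sided. Adjusted p-values are Benjamini-Hochberg values over the 14 motifs, the 8-mers, the 33 lists or the 10 biotypes, and 0.05 was the threshold. Intervals are exact 95% binomial intervals. They cover counting error over peaks or genes only, since peaks and genes are not independent replicates.

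Genes were named by a rule fixed before the data were examined. It takes the 20 highest-signal conservative peaks found in both replicates' own lists with the nearest protein-coding gene, up to 4 members with the highest promoter signal of each list past the threshold, 16 genes of vulval and excretory development with or without a peak, and up to 4 members with a promoter peak of the Ras, Notch, Wnt, Hox, vulval and excretory lists. Other genes named in the text, the highest nuclear peaks among them, were chosen after their values were seen. The signal quoted for a replicate is the highest signal of a peak of that replicate's own ranked list that overlaps the conservative peak.

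Each result was recomputed with the series list, with each replicate's own list in place of the other, with other promoter windows, motif windows, motifs, control sequences, placements and backgrounds, and, chosen after the data were seen, at an IDR of 0.001 or less, without mitochondrial peaks, without peaks near tRNA genes with only the peaks found in both replicates' own lists, with 1 peak kept of those that carry the same signals in both lists compared, with the 300 highest signals away from tRNA genes, and with random placement as the expectation of gene biotypes. The planned stricter threshold of 0.01 is the one that the lists already hold, so it moved nothing.

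The statistics were tested on simulated data with known answers. In 20 simulations with 30% of a list's members hit against 5% of other genes, the list of 79 cytosolic ribosomal proteins was called in 20 and the list of 33 splicing genes in 18, and 4 of 600 unchanged lists were called. Placing a share of the 2243 nuclear summits in promoters returned a share of 42.9%. The simulated share was counted from the same summits, so this match checks the counting alone. A test of 18800 8-mers in randomly placed windows called 0. Such windows lie in the same kind of sequence as their flanks, which real summits need not do. That simulation therefore does not cover calls due to base composition. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.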

Results

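LIN-1 is an ETS-domain transcription factor that acts at the end of the Ras and ERK signalling pathway in the worm, with known roles in the development of the vulva and of the excretory duct. Its binding was measured in whole L4 larvae by ChIP-seq, per the description against a GFP tag, in 1 group of 2 biological replicates. The files hold peaks and no read totals, so the number of peaks is the only sign of depth. Replicate 1 had 1079 thresholded peaks out of 37781 ranked ones and replicate 2 had 1348 out of 33854. The conservative list, in which a peak had to rank alike in both replicates, held 2267 peaks of 48593 ranked ones, and the series list held 2329. Conservative peaks covered 649 kb in all. Among them, 132 (5.82%) repeated both replicate signals of a stronger neighbour and had a median signal of 9.39, so that the list held 2135 peaks with signals of their own. Of all 2267 conservative peaks, 2243 lay on the nuclear chromosomes, with a median signal of 73.8 (quartiles 60.6 and 96.1), and 24 on the mitochondrial genome, with a median signal of 572. A conservative or series peak has a single signal value, so no SD is given for it.

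The first comparison was that of the replicates with each other. Among nuclear peaks found in both replicates' own lists, the one with the highest signal, upstream of rpl-3, which encodes a protein of the large ribosomal subunit, had a signal of 224 in replicate 1 and 299 in replicate 2, and the next, between rpl-20 and Y17G9B.5 had 158 and 204. Of the replicate 1 peaks, 692 of 1079 overlapped a replicate 2 peak, or 64.1% (interval 61.2 to 67%), against 2.23% ± 0.333 (SD, n = 1000 placements) for peaks placed at random. No placement exceeded 3.43% (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). In the other direction 697 of 1348 replicate 2 peaks, or 51.7%, overlapped a replicate 1 peak. Of the 2267 conservative peaks, 701 overlapped peaks of both replicates' own lists, 295 of replicate 1 only, 479 of replicate 2 only, and 792 of neither. The own lists were thresholded within a replicate and held fewer peaks. A peak in neither of them therefore need not be missing from a replicate.

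Across the 2267 conservative peaks, the signals of the 2 lists from which it was made had a Spearman correlation of 0.481 and a Pearson correlation of 0.708 on the log2 scale. Without the mitochondrial peaks these values were 0.465 and 0.603. The median difference between the lists was 1.26-fold. These are correlations across peaks, which are not independent replicates, and peaks that passed the threshold were selected for alike ranks. Over all 48593 ranked peaks the Spearman correlation was 0.318.

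**Figure D1:**
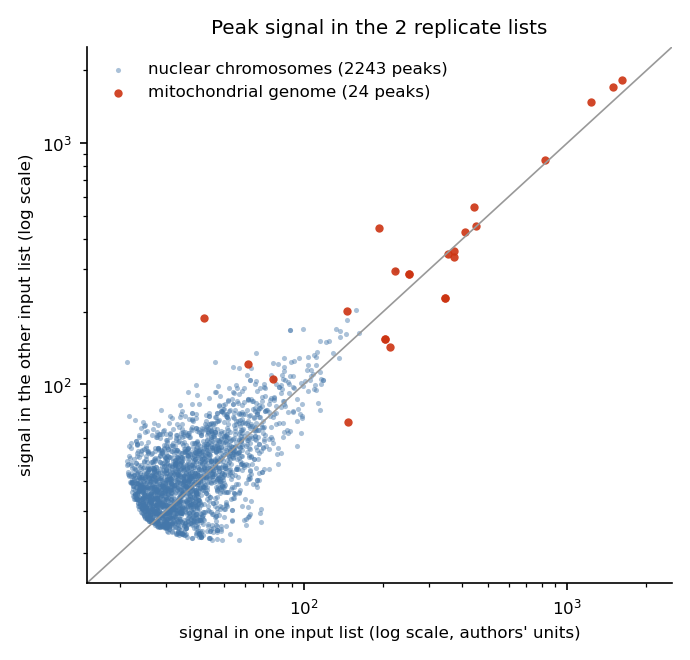
Signal of each of the 2267 conservative peaks in the 2 lists compared, on log axes in the authors' units, with the line of equal signal in grey. The 24 mitochondrial peaks (red) include the highest signals, and the 2243 nuclear peaks (blue) form a cloud whose Spearman correlation is 0.465.

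Within the conservative list, the highest signals lay on the mitochondrial genome, and the highest 2 in the nucleus upstream of rpl-3 and between rpl-20 and Y17G9B.5. Of the 20 highest peaks found in both replicates' own lists, 18 were mitochondrial, and the highest of all, with a signal of 3341, lay at positions 13052 to 13347 of that genome, with its summit in the coding exon of the gene WBGene00010967. The remaining 2 were the rpl-3 peak (chromosome III, 3867453 to 3867679, signal 516, summit 294 bp upstream of the gene start) and the peak between Y17G9B.5 and rpl-20 (chromosome IV, 4749974 to 4750176, signal 353.5, summit 172 bp upstream of Y17G9B.5). Among the next nuclear peaks, chosen after their values were seen, were intergenic sites 56 bp upstream of tasp-1 (chromosome III, 10759143 to 10759352, signal 333), 143 bp upstream of F44E5.4 (chromosome II, 11759318 to 11759529, signal 323) and 61 bp upstream of xbp-1, a transcription factor of the unfolded protein response (chromosome III, 4193636 to 4193854, signal 303). The list went on with rpl-35 (signal 297), cdc-48.1, an ATPase that unfolds ubiquitinated proteins (signal 277.5), rpl-15 (signal 260), mog-4 (signal 236.5) and cbp-1, a histone acetyltransferase (signal 234). One of these nuclear peaks lay within an intron of pxn-1, over the snoRNA gene ZK994.7, with a signal of 302, and another at rpr-1, the RNA of ribonuclease P, with a signal of 240. Because the control experiment was not used here, signal from sources other than LIN-1 binding was not told apart at the mitochondrial or nuclear peaks.

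The second comparison asked where in the genome the summits lay. Promoter windows of protein-coding genes held 928 of 2267 summits, or 40.9% (interval 38.9 to 43%), which was 1.88 times the 21.8% ± 0.877 (SD, n = 1000) found for random placements (permutation p = 0.002, the smallest that 1000 placements can give two-sided). Among the 909 nuclear promoter summits, 833 lay upstream of the nearest gene start, at a median distance of 260 bp. The window reaches 1000 bp upstream and only 200 bp downstream, so most positions in it are upstream, and no placement was run for this count. By annotation class, 53.1% of nuclear summits were intergenic, against 34.6% of the genome, and 15.7% were in non-coding exons, against 3.53%. Coding exons held 4.77% of summits against 24.6% of the genome, and introns 21.3% against 32.5%. The 5′ UTRs held 2.50% against 1.43%, and 3′ UTRs 2.72% against 3.32%.

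Chromosome X held 483 of 2243 nuclear summits, or 21.5% (interval 19.9 to 23.3%), against 17.7% of the genome (p = 2.83e-06, exact binomial test). Chromosome III was also above its share, with 16.3% against 13.8% (p = 0.000661, exact binomial test), and chromosomes IV and V were below, with 15.6% against 17.4% (p = 0.018) and 16.8% against 20.9% (p = 1.32e-06) in exact binomial tests. Among summits more than 200 bp from any tRNA gene, X held 17.8%, and its excess was no longer past the threshold against its share of the genome (p = 0.837, exact binomial test). X holds 13.7% of protein-coding genes, and both shares of summits on X lay above that. On the autosomes, the middle 50% of the chromosomes, where most conserved and widely expressed worm genes lie, held 1113 of 1760 summits, or 63.2% (interval 60.9 to 65.5%), against 50.1% ± 1.23 for random placements and 55.8% for placements within promoter windows (permutation p = 0.002, the smallest that 1000 placements can give two-sided).

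The third comparison set the genes with a promoter summit against 33 lists of genes. A promoter summit was found for 1049 of 19973 nuclear protein-coding genes, or 5.25%. Cytosolic ribosomal proteins led: 25 of 79 had a promoter summit, or 31.6% (interval 21.6 to 43.1%), against 5.15% of other genes (adjusted p = 2.08e-12, Fisher's exact test). The highest were rpl-3, rpl-20, rpl-35 and rpl-15, with signals of 516, 353.5, 297 and 260, and 15 of the 25 were in both replicates' own lists. In contrast, chemoreceptor genes, which are expressed in sensory neurons, were depleted, with 13 of 1308 or 0.994% (adjusted p = 9.74e-16, Fisher's exact test). The highest of these 13 were srz-62 with a signal of 183, sre-23 with 177, srv-1 with 116.5 and srh-269 with 109.

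A further 5 lists were above the rest of the genes. Heat shock and endoplasmic reticulum chaperones had 10 of 51 members with a promoter summit (19.6%, adjusted p = 0.003 in Fisher's exact test), led by hsp-3 with a signal of 221, dnj-13 with 216.5, the mitochondrial chaperone hsp-60 with 163 and dnj-9 with 129. Translation initiation and elongation factors had 8 of 37 (21.6%, adjusted p = 0.0046 in Fisher's exact test), led by eef-1G with 151, eif-3.C with 109, eef-1A.1 with 96.2 and eef-1A.2 with 79.8. Oxidative phosphorylation genes had 8 of 45 (17.8%, adjusted p = 0.0142 in Fisher's exact test), led by cox-5A with 178, cox-5B with 142.5, nduf-2.2 with 138 and atp-1 with 125. Subunits of the vacuolar ATPase, the proton pump of lysosomes and of the excretory canal, had 5 of 20 (25%, adjusted p = 0.0174 in Fisher's exact test), with vha-1 at 104.5, vha-13 at 92.3, vha-8 at 89.1 and vha-12 at 89. The synMuv chromatin genes, repressors of vulval fate that act against the Ras pathway, had 5 of 22 (22.7%, adjusted p = 0.0232 in Fisher's exact test). They were lin-53 with a signal of 162, lin-9 with 144, lin-54 with 131, lin-52 with 62.6 and efl-1 with 58.9, all members of or associated with a complex of retinoblastoma and E2F-type proteins. The lin-54 summit also lay in the promoter window of rpl-12, and the vha-1 summit in that of sqv-3, so that a peak could count for more than 1 gene. The lists of ribosomal proteins and of chemoreceptors passed the threshold under every alternative run. The other 5 calls were lost among genes with at least 500 bp of upstream intergenic sequence (lowest adjusted p = 0.0722, Fisher's exact test), where fewer genes were tested and shares were 20% for heat shock, 23.5% for translation, 25% for oxidative phosphorylation, 21.4% for vacuolar ATPase and 16.7% for synMuv genes, and with the nearest start alone so were those of heat shock (0.144), oxidative phosphorylation (0.107), vacuolar ATPase (0.101) and synMuv genes (0.107). By Fisher's exact test the synMuv call was also lost in either replicate's own list (adjusted p = 0.12 and 0.0927) and at an IDR of 0.001 (0.107), that of translation factors in replicate 1's list (0.245), at that IDR (0.107) and with peaks of both lists (0.116), and that of vacuolar ATPase in replicate 1's list (0.26) and with peaks of both lists (0.162). Fewer peaks entered there: 1079 and 1348 in the replicates' own lists, 1177 at that IDR and 701 in both lists, against 2267.

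**Figure D2:**
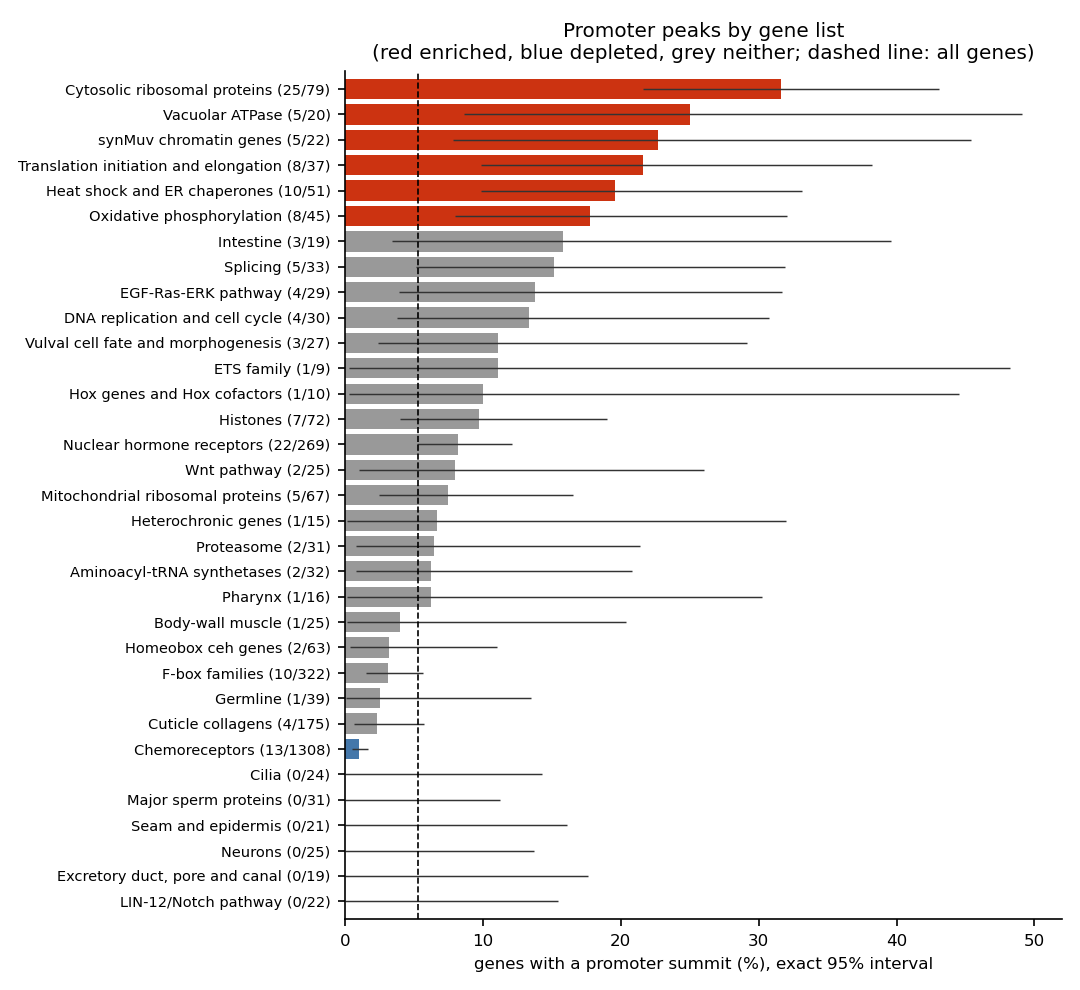
Share of the members of each of 33 gene lists that had a summit in the promoter window, with exact 95% intervals; members with a summit and members tested are given in brackets. The dashed line marks the 5.25% of all genes; the list of cytosolic ribosomal proteins lies highest, at 31.6%, and the chemoreceptors lie at 0.994%.

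The lists of the Ras, Wnt and Notch pathways and of Hox, vulval and excretory genes were not past the threshold. The EGF, Ras and ERK pathway had 4 of 29 members with a promoter summit (13.8%, interval 3.89 to 31.7%, adjusted p = 0.206 in Fisher's exact test). These were cnk-1 with a signal of 151 (chromosome III, 10270903 to 10270986), the adaptor sem-5 with 111 (chromosome X, 7962233 to 7962528), eor-2 with 81.7 (chromosome X, 14602719 to 14603014) and lin-7 with 48.6 (chromosome II, 14349531 to 14349826), each intergenic. The vulval list had 3 of 27, which were sqv-3 with 104.5, the homeobox gene ceh-2 with 88.4 and sqv-8 with 60.9. The Wnt pathway had 2 of 25, mig-5 with 114.6 and wrm-1 with 63.7, and the Hox list had 1 of 10, the cofactor gene ceh-60 with 70.7. The peaks at cnk-1, sem-5, eor-2, sqv-3 and mig-5 were in both replicates' own lists. That at ceh-2 was in replicate 1's list only. No peak of replicate 2's own ranked list overlapped it, although it had passed the comparison of the replicates. Those at lin-7, sqv-8, wrm-1 and ceh-60 were in neither list. None of the 22 Notch genes or 19 excretory genes had a promoter summit, which leaves room for shares up to 15.4% and 17.6%. With windows that reached 2000 bp upstream and 500 bp downstream, the Ras list passed the threshold (24.1%, adjusted p = 0.0228, Fisher's exact test).

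None of the 16 genes fixed beforehand for their place in vulval and excretory development had a summit in the promoter window, and 4 had one in the gene body. Only 5.25% of all nuclear protein-coding genes had a promoter summit, so its absence from 16 genes does not show that they are avoided. The lin-1 gene itself (chromosome IV, 2275861 to 2300286, minus strand) had 3 intronic summits, 1 of which, with a signal of 4.94, repeated the replicate signals of its neighbour with 81.3. The highest, at 2284459 to 2284754, had a signal of 91.4 (27.9 in replicate 1 and 68.0 in replicate 2) and lay 15679 bp downstream of the gene start. At egl-17, a fibroblast growth factor gene of vulval cells (chromosome X, 489685 to 492318), a peak at 489775 to 490070 had a signal of 108, with 43.5 in replicate 1 and 63.1 in replicate 2, and its summit lay 238 bp downstream of the gene start, just outside the promoter window. A second egl-17 peak, with a signal of 79.1, lay 1894 bp upstream. The heterochronic gene lin-14 had 2 intronic summits with signals of 112.4 and 72.5, and mpk-1, which encodes ERK, had an intronic summit with a signal of 68.2. Of the peaks at lin-1, egl-17, lin-14 and mpk-1, only the egl-17 peak of 108 was in both replicates' own lists. The lin-1 peaks, the lin-14 peak of 112.4 and the egl-17 peak of 79.1 were in replicate 2's list only. The lin-14 peak of 72.5 and the mpk-1 peak were in neither. The nearest summits to the starts of lip-1 (3.67 kb) and lag-2 (4.97 kb) had signals of 66.0 and 77.3. For lin-39, lin-31, lin-12, let-23, lin-3, lin-48, eor-1, nhr-25, lin-11 and bar-1 the summit nearest the gene start lay between 14.4 kb (let-23) and 62 kb (bar-1) from that start.

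The remaining lists were also not past the threshold. Nuclear hormone receptor genes had 22 of 269 (8.18%, adjusted p = 0.139, Fisher's exact test), with nhr-68 highest at a signal of 174. By the same Fisher's exact test, splicing genes had 5 of 33 (adjusted p = 0.114), intestine genes 3 of 19 (adjusted p = 0.206), which were cpr-1, the intestinal GATA factor gene elt-2 and act-5, and genes of DNA replication and the cell cycle 4 of 30 (adjusted p = 0.206), which were cyd-1, pcn-1, mcm-2 and cye-1. Cuticle collagens had 4 of 175 (2.29%, adjusted p = 0.22, Fisher's exact test). Neuronal, cilium, seam and epidermis, and major sperm protein genes had 0 of 25, 0 of 24, 0 of 21 and 0 of 31. Histone genes had 7 of 72, F-box genes 10 of 322, mitochondrial ribosomal proteins 5 of 67 with mrpl-39 highest at 185.7, and homeobox genes, aminoacyl-tRNA synthetases and proteasome subunits 2 of 63, 2 of 32 and 2 of 31. Germline, muscle, pharynx, heterochronic and ETS family genes had 1 of 39, 1 of 25, 1 of 16, 1 of 15 and 1 of 9.

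The fourth comparison was between gene biotypes, and tRNA genes had by far the highest share with a summit nearby. A summit lay within 200 bp of 290 of 634 tRNA genes, or 45.7% (interval 41.8 to 49.7%), against 6.13% of 19985 protein-coding genes (adjusted p = 8.52e-162, Fisher's exact test). Genes of snoRNAs, which guide modification of ribosomal RNA, had 78 of 346 (22.5%, adjusted p = 1.18e-22), and snRNA genes 23 of 129 (17.8%, adjusted p = 8.24e-06, Fisher's exact test). Random placement gave 2.97% of tRNA, 1.22% of snoRNA and 1.08% of snRNA genes. The observed shares were 15.4, 18.4 and 16.4 times those. Genes of lincRNAs (9.28%) and of the class ncRNA (6.23%) did not differ from protein-coding genes past the threshold (adjusted p = 0.103 and 0.821, Fisher's exact test). Both still lay above random placement, which reached at most 7.22% and 1.61%. The highest signal at a nuclear tRNA gene, 191, lay on chromosome X (3036104 to 3036239) over 1 of a pair of tRNA genes, with 114 in replicate 1 and 83.9 in replicate 2. The highest snoRNA signals were at ZK994.7 (302), T03F7.8 (231) and C51F7.4 (214), whose peak also counted for its neighbour C51F7.3. The highest snRNA signals were at sls-2.4 (168.5), sls-2.2 (164) and sls-2.1 (161), genes of a spliced leader RNA. The snoRNA and snRNA calls were lost when the summit had to lie inside the gene body (adjusted p = 0.687 and 0.148, Fisher's exact test).

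Genes of piRNAs, of which 32 of 15363 had a summit nearby (0.208%), and pseudogenes, with 23 of 2128 (1.08%), lay below protein-coding genes (adjusted p = 7.16e-258 and 1.96e-29, Fisher's exact test) and below random placement, which gave 0.838% and 3.85%. Genes of miRNAs were also below protein-coding genes, with 7 of 261 (2.68%, adjusted p = 0.0301, Fisher's exact test), but not below random placement, which gave 1.19% (range 0 to 3.45%), and that call was lost in the series list and in both replicates' own lists. They included mir-2214 with a signal of 111, mir-51 with 101 and mir-60 with 93.7. By place, 259 nuclear summits were within 200 bp of a tRNA gene and 106 near a snoRNA, snRNA or rRNA gene but not a tRNA gene, with median signals of 79.8 and 96.0, against 74.1 for the other promoter summits and 70.2 elsewhere.

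**Figure D3:**
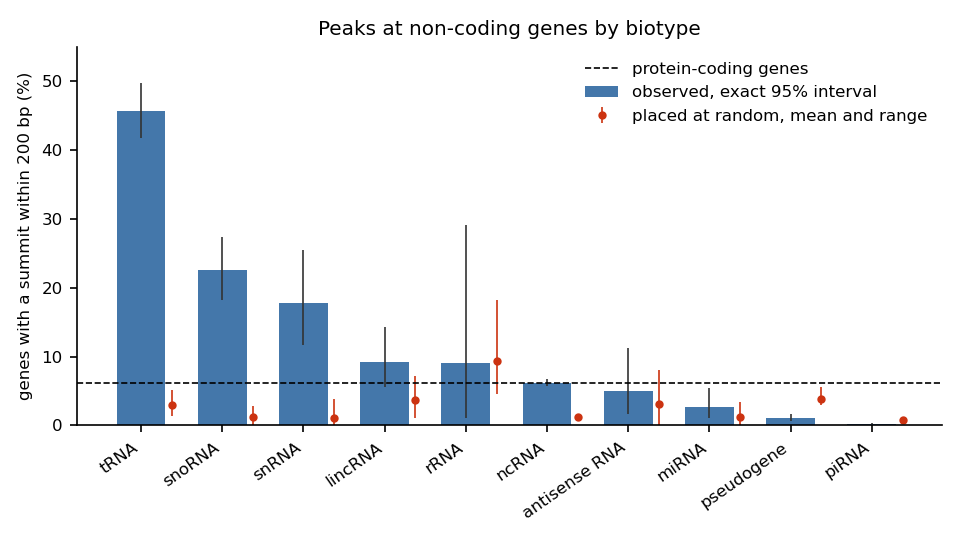
Share of non-coding genes of each biotype with a summit within 200 bp (bars, exact 95% intervals), the mean and range of 100 random placements (red), and the 6.13% of protein-coding genes (dashed line). The tRNA genes reach 45.7%, the snoRNA genes 22.5% and the snRNA genes 17.8%, all above the placed ranges. The lincRNA genes, at 9.28%, and the ncRNA genes, at 6.23%, also lie above theirs.

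The fifth comparison asked which sequences lay at the summits. The ETS core CCGGAAR, to which ETS-domain proteins bind, was found within 50 bp of 56 of 2267 summits, or 2.47% (interval 1.87 to 3.20%), against 2.60% of flank windows (odds ratio 0.948, p = 0.807, Fisher's exact test). Against dinucleotide-shuffled summit windows the odds ratio was 1.69 (p = 0.00495, Fisher's exact test). The longer CCGGAAGT was at 4 summits, and the relaxed MGGAAG at 7.90% against 7.15% in flanks (p = 0.28, Fisher's exact test). Peaks with CCGGAAR had a mean log2 signal of 6.33 ± 0.98 (SD, n = 56) and those without it 6.18 ± 0.98 (n = 2211), a difference of 0.15 that did not pass a permutation test (p = 0.248). With 1 peak kept per pair of replicate signals, an alternative added after the data were seen, the difference was 0.18 (permutation p = 0.0358).

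Motifs of other families were more frequent at the summits. The E-box CACGTG was at 7.01% of summits against 1.79% of flanks (adjusted p = 2.09e-25, Fisher's exact test) and GATA sites, WGATAR, at 33.3% against 20.3% (adjusted p = 7.95e-30). In the same Fisher's exact test, GAGAGAGA was at 4.72% against 0.971% (adjusted p = 6.62e-21), GGGCGG at 5.34% against 1.54% (adjusted p = 3.39e-17), the E2F site TTSSCGC at 6.26% against 3.42% (adjusted p = 3.34e-07) and the AP-1 site TGASTCA at 1.32% against 0.507% (adjusted p = 0.00106). Lower at summits in Fisher's exact test were Hox-Pbx sites, TGATNNAT, at 5.47% against 7.54% (adjusted p = 0.00206), TCF sites, CTTTGWW, at 6.13% against 9.11% (adjusted p = 3.49e-05), and the splice acceptor TTTCAG at 7.37% against 18.9% (adjusted p = 2.44e-38). Against shuffled sequence the E-box, GATA, GAGA, GGGCGG and TCF results stayed past the threshold in the same direction, while those of E2F, Hox-Pbx, AP-1 and the splice acceptor did not. In Fisher's exact test the AP-1 call was also lost in both replicates' own lists (adjusted p = 0.119 and 0.149) and with peaks of both lists (0.077), and that of Hox-Pbx in replicate 1's list (0.164). These settings held 1079, 1348 and 701 peaks against 2267 in the main list, so a lost call need not mean a smaller difference. The forkhead site TGTTTAC (1.72% against 1.46%) and the CSL site YRTGRGAA of the Notch pathway (2.60% against 2.82%) did not differ from flanks past the threshold, although the forkhead site did in replicate 2's own list (odds ratio 1.85, adjusted p = 0.025, Fisher's exact test).

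**Figure D4:**
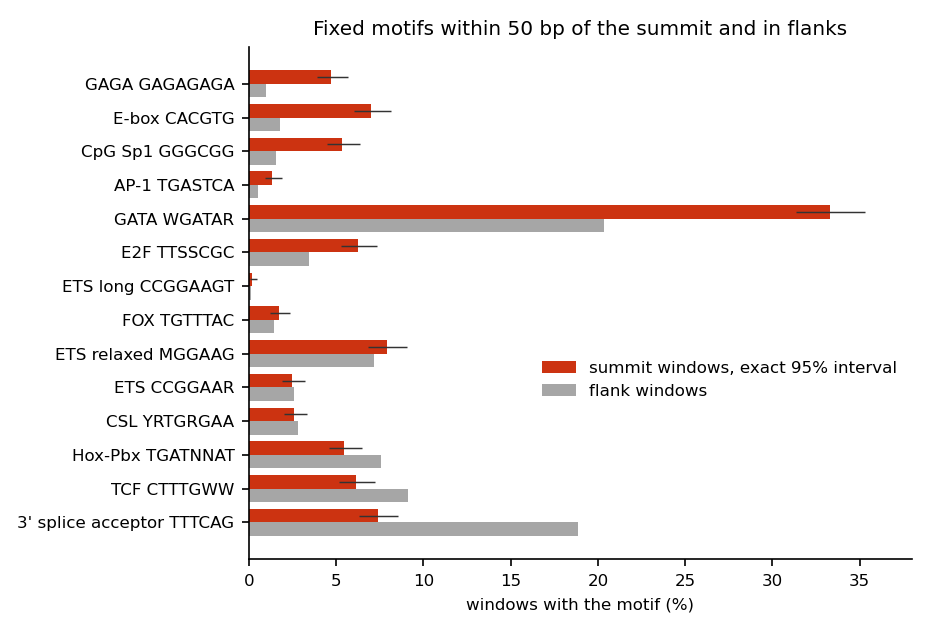
Share of summit windows (red, exact 95% intervals) and flank windows (grey) that hold each of the 14 fixed motifs, in order of the odds ratio. E-box, GATA and GAGA sites are more frequent at summits, and the ETS core is at 2.47% of summits and 2.60% of flanks.

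Of 21388 8-mers tested, 1826 were more frequent at summits than in flanks and 1116 less frequent, at an adjusted p under 0.05. The first were a pair of GATA words, TCTTATCA (6.53% against 0.684% of flanks, adjusted p = 7.7e-39, Fisher's exact test) and ACTGATAA at 154 (6.79% against 0.949%). They were followed by a GACGCAG family, AGACGCAG at 142 summits (6.26% against 0.794%), GAGACGCA at 132, GACGCAGA at 117 and AGAGACGC at 97. The word AGTGGTTA was at 81 summits (3.57% against 0.199%), CTGATAAG at 98, CTGAGCTA at 73 and CTGATAAC at 75. Without the summits near tRNA genes CTGAGCTA was no longer in excess (odds ratio 0.499, adjusted p = 0.792, Fisher's exact test) and the odds ratio of AGTGGTTA fell from 18.6 to 7.60, while the GATA and GACGCAG words remained, led by TCTTATCA at 146 of 1984 summits (7.36%). No 8-mer was tested against shuffled sequence, so a part played by base composition in these counts stays open.

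**Figure D5:**
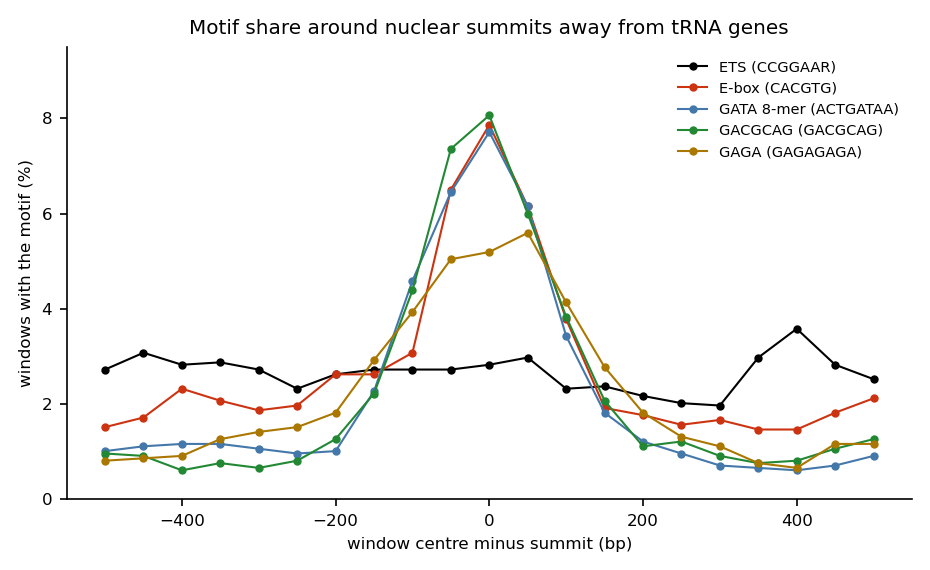
Share of 101 bp windows with each motif against the distance of the window from the summit, in bp, for 1984 nuclear peaks away from tRNA genes. The GATA 8-mer and GACGCAG were picked for their excess at summits over flanks in these same data, so their rise at the summit is no separate result. The E-box, GATA and GACGCAG words peak at the summit, where they reach 7.86, 7.71 and 8.06%; GAGA is at 5.19% there and highest 50 bp away, at 5.59%, and the ETS core is at 2.82% at the summit.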

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

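The ranked list behind the conservative list held 71 more peaks past the authors' threshold than the conservative list itself, so that a signal lay in data that the comparisons did not use. The highest of them, with a signal of 1857, lay on chromosome X at 15810949 to 15811202, against a highest nuclear signal of 516 in the list that was used. Their median signal was 93.4 against 73.8 for listed nuclear peaks, and 4 of the 5 highest nuclear signals past the threshold were among them. The series list and the lists of replicates 1 and 2 left out 68, 62 and 44 such peaks. The sources used here do not say why. These regions may have been excluded on purpose, so they cannot be read as binding sites that were missed.

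The tests below on X, tRNA gene bodies, the highest-signal peaks and ETS sites at tRNA genes were chosen after the result was seen. Those on the sequence of the flanks and on tRNA genes with 50 bp on each side were fixed before. The design has 1 group, so no biological explanation based on groups was tested.

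The ETS core was no more frequent at summits than in flanks, although LIN-1 is an ETS-domain protein. Summits that lie too far from the bound site are argued against, since windows of 100 bp each side gave an odds ratio of 0.948 (interval 0.748 to 1.20). The excess over shuffled sequence may belong to the genome around the peaks: the flanks themselves held the core more often than their own shuffles (odds ratio 1.66, interval 1.28 to 2.13), close to the 1.69 at summits. Dilution by weaker peaks stays open, because the 300 highest signals away from tRNA genes gave an odds ratio of 2.21 with an interval of 0.949 to 5.18 (p = 0.0596, Fisher's exact test). Whether the tagged protein reached many of these sites through other proteins was not tested.

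X held more summits than its share of the genome, and peaks near tRNA genes are a candidate explanation. X has 276 of 612 nuclear tRNA genes, 49.8% of the summits near tRNA genes were on X, and away from them X held 17.8% (interval 16.2 to 19.6%) against 17.7% of the genome. That interval still lies above the 13.7% of protein-coding genes on X, so an excess over the share of genes is not accounted for by tRNA genes alone. A higher rate of peaks per tRNA gene on X, 50.7% against 42.3% on autosomes (p = 0.0416, Fisher's exact test), cannot be the whole of it, since with X scaled to the autosomal rate its share would still be 20.8% (interval 19.1 to 22.5%).

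Peaks were far more frequent at tRNA genes than at protein-coding genes, and reads shared between identical copies could give them; sequences with 50 bp on each side decide nothing, since 610 of 612 are unique (46.2% with a peak). Reads shared between identical gene bodies are argued against as the whole cause, because 39 or 34.8% of the tRNA genes whose body occurs once, away from tRNA genes with copies, had a peak (interval 26.1 to 44.4%), above the 6.25% that random placement reached at most. A body counted as occurring once when no other nuclear tRNA gene had exactly its sequence. Reads shared between near copies therefore stay open. As part of the cause reads shared between identical bodies stay open too, since gene bodies that occur once had a peak in 36.4% of 143 and those with copies in 49.0% of 469 (p = 0.00954, Fisher's exact test). ETS sites at tRNA genes are argued against for these summits, since 0% of 259 summits near tRNA genes held CCGGAAR (upper bound 1.41%), against 2.82% of other nuclear summits. The bound treats the 259 windows as independent, which they need not be, since 469 of the 612 tRNA gene bodies have copies. A signal that strongly transcribed genes give with any antibody stays open, because the control experiment was not used here.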

How the results depend on the processing

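Settings with an IDR of 0.001, without mitochondrial or tRNA-near peaks, with peaks of both lists only, with 1 peak per pair of replicate signals, with the 300 highest signals, and with random placement as the expectation of biotypes were added after seeing the data. The replicate overlap, the promoter share and the chromosome centre share kept their direction and side of the threshold under every alternative run, and of 102 values of the main results 80 did so or stayed within their margin. The cause of the following changes was not tested unless stated. At an IDR of 0.001 there were 1177 peaks and 921 enriched 8-mers, with peaks of both lists 317 8-mers, and with 1 replicate's own list 730 to 987, from fewer peaks. The signal correlation over all ranked peaks was 0.318. X held 17.8% without tRNA-near peaks. With the nearest start alone 3 gene lists were past the threshold, and with long upstream regions 2, from fewer genes. The ETS odds ratio of 0.948 moved above 1 with the series list (1.09), at an IDR of 0.001 (1.05), without tRNA-near peaks (1.08), with peaks of both lists (1.13), for CCGGAAGT (1.60), for MGGAAG (1.11), against shuffles (1.69) and for the 300 highest signals (2.21), and was 0.941 to 1.05 without a replicate. Only that against shuffles passed 0.05. The log2 signal difference with the motif turned to -0.0395 with the series list, -0.44 for CCGGAAGT and -0.0585 with 100 bp each side, and lay between 0.09 and 0.13 without a replicate. It was 0.18 with 1 peak per pair of replicate signals, the only alternative of this result to pass 0.05 (permutation p = 0.0358), where the weak repeated peaks no longer entered; every other result kept its label there. Of single items, CTGAGCTA fell to an odds ratio of 0.499 without tRNA-near peaks, miRNA genes lay at 2.26 times random placement but within its range, AP-1 had 0.808 and the splice acceptor 1.03 against shuffles, forkhead 0.93 without tRNA-near peaks, 0.898 with peaks of both lists and 1.85 without replicate 1 (adjusted p = 0.025, Fisher's exact test), and CSL 1.11 and 1.24 without a replicate. The Hox list, never past the threshold, held 0% in each replicate's list, at an IDR of 0.001, with peaks of both lists and with 500 bp windows, and the Wnt list 4% with 500 bp windows and 4.55% with long upstream regions. For 71 named genes, 648 of 710 answers on whether a promoter peak was present stayed as reported. No paired analysis was possible because there is only 1 group. Read depth per replicate is not given in the sources used here, so a missing peak does not show a missing site.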

Other observations

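The tests in this part were fixed before their results were seen, on patterns already found in the same data, and the odds ratios over flanks were compared after. The sequence words that mark the summits were spread unevenly over kinds of places. TGATAA, a core GATA site, was at 29.1% of 1051 summits outside promoters and away from small RNA genes, at 22.2% of 827 promoter summits, at 10% of 259 summits near tRNA genes and at 2.83% of 106 summits near snoRNA, snRNA or rRNA genes. The E-box CACGTG was at 9.90% of summits elsewhere, 6.17% of promoter summits and 1.16% of those near tRNA genes. In a test of whether the words belong to different kinds of places, 3 of the 4 words, the E-box, GATA and GAGAGAGA, were less frequent in promoters than elsewhere (adjusted p = 0.00541, 0.00338 and 0.00541, Fisher's exact test). That test did not take the flanks into account, which held the E-box at 1.39% in promoters and 2.05% elsewhere and GAGAGAGA at 0.544% and 1.33%. The odds ratios over flanks were 4.66 in promoters and 5.26 elsewhere for the E-box, 7.12 and 5.45 for GAGAGAGA, and 2.50 and 4.58 for TGATAA, and the differences between them were not tested. GACGCAG did not differ (8.34% in promoters and 8.09% elsewhere, adjusted p = 0.866, Fisher's exact test) and was also at 5.66% of summits near snoRNA, snRNA or rRNA genes against 0.943% of their flanks, but near tRNA genes it was at 0.772% of summits and of flanks alike.

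Among ribosomal protein genes with a promoter peak, 1 of 25 had TGATAA, against 18.9% of the other genes with a promoter peak (p = 0.0666, adjusted p = 0.799, Fisher's exact test). The hypothesis that gene lists with promoter peaks differ in which word their peaks hold found no pair past the threshold, 0 of 24, with a lowest adjusted p of 0.799. With 5 to 25 genes per list only large differences could be seen.

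Promoter summits may prefer windows shared by 2 or more genes. Of 909 nuclear promoter summits, 206 or 22.7% lay in the windows of 2 or more genes, against 10.9% for random placement within promoter windows (range 7.70 to 14%, permutation p = 0.002, the smallest that 1000 placements can give two-sided). The peaks shared by rpl-20 and Y17G9B.5, by lin-54 and rpl-12 and by sqv-3 and vha-1 are of this kind. The preference was not tested against the level of transcription of these genes, which was not analysed here.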
